A study of Oncorhynchus mykiss with 12 samples.

How the data were processed

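The series holds single-cell RNA sequencing of mononucleated cells from the white muscle of rainbow trout (Oncorhynchus mykiss) in 12 libraries, named by body weight: 10 g (3 libraries), 100 g (2), 500 g (2), 1000 g (2) and 1500 g (3). Per the labels, 20 to 80 g of muscle were digested with collagenase and trypsin, so that a library of 10 g fish must hold several fish. A Percoll gradient was meant to remove debris and red blood cells, the cells were kept overnight in the cold, and libraries were made with the 10x Genomics 3' kit. Nothing in the labels names a batch, a sequencing date or the fish behind a replicate. Reads had been aligned to the USDA_OmykA_1.1 assembly, and the deposited count matrices were made by the authors with Cell Ranger 7.0.1 according to the submitters' processing notes. The values are raw UMI counts per gene and barcode, already reduced by the authors to called cells. Each library holds a whole multiple of 100 barcodes, by a rule that is not given in the sources used here. Libraries shared at most 0.417% of the barcodes of the smaller one.

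The files hold 49500 barcodes and 70107 genes, of which 47519 are named only by a locus number. Depth fell with body weight, so that depth and weight cannot be separated by design. The 10 g libraries held 97.1, 48.8 and 49.8 M UMIs (1 M is 1e6) with medians of 12348.5, 8632.5 and 9422 per barcode, and the 100 g libraries 103.1 and 106.9 M (10555 and 9752). Those of 500 g held 55.0 and 48.6 M (7029.5 and 4776.5), of 1000 g 26.5 and 27.4 M (4707.5 and 6229.5), and of 1500 g 10.7, 28.0 and 29.1 M (6052.5, 5713.5 and 5011). Counts were read in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5. Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were used. In each library the barcodes with the highest scrublet score, as built into scanpy, were marked as doublets at an assumed rate of 0.8% per 1000 barcodes (0.96 to 5.04% of a library, 11 to 307 barcodes), and 46443 cells were kept, 1156 to 5778 per library.

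Counts were scaled per cell and put on the log scale, 2000 variable genes were reduced to 30 principal components, and cells of all libraries were clustered together on 20 nearest neighbours (scikit-learn 1.9.0) with leidenalg 0.10.2 at a resolution of 0.5. Each of the 25 clusters was compared with 17 fixed marker lists. It took the name of the list with the highest mean log2 fold over the mean of the other clusters when that mean was at least 1 and at least 3 markers reached 5 CPM and a 2-fold level. Its 10 leading genes also had to hold no more markers of other lists than of its own. Clusters with a median UMI count under 1/3 of that of their libraries and no own marker among the 10 were to stay unnamed, and no cluster met this. The mural and epithelial lists had only 2 listed genes each that could be matched, fewer than the 3 needed. Neither could therefore name a cluster. Unnamed clusters keep their number. The ending "-like" marks that a class rests on transcripts alone. Counts of a class were summed per library where it had at least 20 cells, and classes with at least 8 such libraries, 2 or more of them at each end, were tested.

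Sums were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F tests, Benjamini-Hochberg adjusted p under 0.05). The trend fit used log10 body weight as 1 slope. A second fit used the 5 weights as groups to compare each with 10 g, with 1 shared estimate of the spread. Where a left-out library leaves a weight with 1 library, that library is assumed to vary like the others. The difference of slopes between MuSC-like and fibroblast/FAP-like cells was tested with the library as a block. The library is the replicate throughout, so that each p measures the spread between these libraries. The 15 lists of cell states and the cell type lists were tested on the trend with camera of limma 3.58.1 (preset correlation 0.01, prior count 2), with an estimated correlation and fry beside it. Shares, the summed G2/M and S phase levels and the cycling share were correlated with log10 weight by permutation (100000 draws), with Benjamini-Hochberg adjustment over each family. For the cycling share, cells were thinned to 2000 UMIs and shallower cells left out (0, 15, 51, 39 and 49 MuSC-like cells from the lowest to the highest weight); a cell counted as cycling with at least 3 UMIs of the G2/M list.

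Lists were matched to trout genes by symbol, by symbol with a paralog letter, or by a synonym in the gene table, in which 57661 of the features were found as symbols and 12446 were not. That table gives no product names, so that genes carrying only a locus number and no synonym could not be matched; pcna was 1 of these. The ribosomal list at first took in genes of S6 kinases through their shared prefix. These were taken out after the results had been seen, and no call of that list changed. Named genes were chosen by a rule: an informative symbol, an adjusted p under 0.05, a mean of at least 10 CPM, no overlap between the 10 g and 1500 g libraries, and then the 12 (MuSC-like), 8 (fibroblast/FAP-like) or 3 (other classes) most positive and most negative slopes. Up to 4 called members of each state list were named, with pax7a, pax7b, myf5, myod, myog, mki67 and top2a in any case. After the results had been seen, alternatives for list members were kept to called members, and values in the other classes were given in the comparisons only for genes that kept their call without any 1 library, less falls of tendon, connective tissue, fibre and division genes outside the cells that lead in them, since free RNA was not tested there. Apart from these changes, the lists, the rule, the tests of the comparisons and all alternatives but those named below were fixed before the data were examined; some tests of explanations were chosen later, as stated with them.

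The fits of MuSC-like and fibroblast/FAP-like cells were tested on simulated data built from the libraries, with counts drawn from the real means, library sizes and spread and slopes of 0.5, 1 or 2 put into 200 genes of at least 10 CPM. For the MuSC-like trend (22435 genes) it found 80.6, 97.0 and 98.5% of them, with 6.12% false among the calls. For MuSC-like cells at 1500 g against 10 g (23695 genes) it found 64.2, 97.0 and 97.0% (8.02% false), for the fibroblast/FAP-like trend (18642 genes) 59.7, 98.5 and 100% (3.91%) and for its 1500 g against 10 g (19820 genes) 35.8, 98.5 and 100% (7.14%). The trend difference (18562 genes) found 20.9, 94.0 and 97.0% (7.84%), and camera gave a p under 0.05, unadjusted, for 20 of 500 random lists that had not been shifted (4%). Each simulated gene was drawn independently, so that this cannot show how camera behaves where the members of a list vary together. The trends of the other classes and the middle weights were not simulated. A slope of 1 was thus found in nearly every simulated gene and a slope of 0.5 often missed.

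Alternatives were: DESeq2 1.42.0 as test or for size factors, no filter on low counts, a replicate block, cell filters of 1000 genes and 10%, no filter on genes and mitochondrial UMIs, no doublet removal, a Leiden resolution of 1, expression centred within libraries, equal numbers of cells (190 MuSC-like and 80 fibroblast/FAP-like cells per library), a denominator without erythroid-like cells, the log2 odds scale, cycling limits of 2 and 5 UMIs, no thinning, and each library left out in turn. The single clusters of a class, clusters 0, 7 and 17 together and a denominator without fibre-like clusters were added after seeing the data. The labels of the libraries were also regrouped at random, 100 times for each trend with the real grouping included, and in the 10 splits of the 10 g and 1500 g libraries. The trend difference was not regrouped. Some genes that were tested are not reported. Reads and isoforms were not analysed here, and individual fish could not be told apart. Figures were drawn with matplotlib 3.10.9.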

Results

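Rainbow trout go on forming new white muscle fibres long after hatching, and this hyperplastic growth fades as the fish gain weight. Muscle stem cells (MuSC, the satellite cells of muscle) supply the nuclei of new and growing fibres, and fibro-adipogenic progenitors (FAP) are connective-tissue cells that lie between the fibres. Single-cell counts of mononucleated cells from 12 libraries, from fish of 10 g (3 libraries), 100 g (2), 500 g (2), 1000 g (2) and 1500 g (3), were used to ask which cells and which of their genes changed with body weight. The p-values measure the spread between these libraries, since the labels do not say which of them come from separate fish. A 10 g library must hold several fish. The spread at 10 g is thus one between pools and may not be like that of the heavier fish.

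Of the 46443 kept cells most fell into classes named by their markers. MuSC-like cells (6113 cells, 13.2% of the kept cells) carried pax7a and pax7b, transcription factors that mark satellite cells, with megf10, fgfr4 and met. They joined cluster 3 (3888 cells) and cluster 9 (2225 cells), the latter led by myod2, id1 and cebpd. Myocyte-like cells (3788 cells, 8.16%) carried myog, a regulator of differentiation, and mymk, the fusion protein myomaker, and also myod. At 10 g they held more transcripts of mitosis genes (the G2/M list below) than MuSC-like cells did, 706 against 168 CPM. The name therefore does not mean that these cells had stopped dividing. Tenocyte-like cells (5400 cells, 11.6%) carried scxa, tnmd and thbs4a of tendon. Fibroblast/FAP-like cells (3440 cells, 7.41%) joined cluster 7 (2952 cells), with ngfa, cd209 and tcf21 among its leading genes, and cluster 17 (488 cells), with col11a1a, bgnb and s100b. Erythroid-like (4708 cells), endothelial-like (4217), glia-like (2684), macrophage-like (1043), T/NK cell-like (741), B cell-like (721) and neutrophil-like cells (318) made up most of the rest. The largest cluster without a name, cluster 0 (6354 cells), carried pdgfra and col1a1 of fibroblasts and also sox9 of skeletogenic cells. Its mean log2 fold over the fibroblast/FAP list was 1.62, above those of cluster 7 (1.23) and cluster 17 (1.52). It stayed unnamed because sox9 was among its 10 leading genes. Results for fibroblast/FAP-like cells thus cover clusters 7 and 17 and not all cells with fibroblast markers. Cluster 5 (3587 cells) was led by pvalb2, gapdh and tnnt3a, transcripts of the muscle fibre itself.

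Myocyte-like cells became scarcer as the fish grew, while endothelial-like and neutrophil-like cells took a larger share. Myocyte-like cells made up 16.5 ± 1.18% of the cells at 10 g (mean ± SD, n = 3), 7.94% at 100 g, 5.13% at 500 g, 2.04% at 1000 g and 2.89 ± 1.28% at 1500 g (n = 3). Endothelial-like cells, which line the vessels, went from 1.93 ± 0.724% to 23.2 ± 2.09%, and neutrophil-like cells from 0.114 ± 0.106% to 2.07 ± 0.776%. Tenocyte-like cells went from 18.1 ± 3.46% to 6.04 ± 1.06%. MuSC-like cells held 16.9 ± 0.546% at 10 g and 13.4 ± 2.74% at 1500 g. Of all MuSC-like and myocyte-like cells, the myocyte-like part fell from 49.4 ± 1.48% at 10 g to 17.5 ± 6.68% at 1500 g, with 39.6%, 29.8% and 18.2% at 100, 500 and 1000 g.

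Over the 12 libraries the myocyte-like share fell with log10 body weight (Pearson r = -0.97, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 1.05e-04 over 21 classes). Spearman rho was -0.91 (permutation p = 1e-04, adjusted p = 7e-04), and r was between -0.958 and -0.953 without the 2 libraries farthest from the median weight. The myocyte-like part of the myogenic cells fell likewise (r = -0.95, permutation p = 1e-05, again the smallest possible, in a family of 1 relation). Its rho was -0.91 (permutation p = 1.1e-04), and r was -0.935 to -0.920 without the 2 farthest libraries. The endothelial-like share rose (r = 0.85, permutation p = 9.7e-04, adjusted p = 0.0034). Its rho was 0.95 (permutation p = 1e-05, adjusted p = 2.1e-04), and r without the 2 farthest was 0.794 to 0.816. The neutrophil-like share rose as well (r = 0.73, permutation p = 0.00844, adjusted p = 0.0222), with a rho of 0.91 (permutation p = 1.8e-04, adjusted p = 7.56e-04) and an r of 0.679 to 0.711 without the 2 farthest. The tenocyte-like share fell (r = -0.86, permutation p = 5.8e-04, adjusted p = 0.00244). Its rho was -0.85 (permutation p = 0.00111, adjusted p = 0.00333) and r without the 2 farthest was -0.843 to -0.727. With 3 libraries at each end, the exact test of 1500 g against 10 g cannot give a p under 0.1, and it gave 0.1 for each of these 4 classes. The cells had passed a Percoll gradient meant to remove debris and red blood cells, and the larger fish gave fewer cells and UMIs. The shares describe the recovered cells and not the tissue.

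The macrophage-like share and clusters 12, 20 and 23 moved with weight too, the first of them less securely. The macrophage-like share went from 1.22 ± 0.227% to 3.99 ± 1.92% (r = 0.66, permutation p = 0.0166, adjusted p = 0.0349). Its rho was 0.77 (permutation p = 0.00509, adjusted p = 0.0134), and r was 0.553 to 0.606 without the 2 farthest. By the same permutation test that call was lost without 10 g replicate 1 (adjusted p = 0.0666), 10 g replicate 2 (0.084), 10 g replicate 3 (0.0773), 100 g replicate 2 (0.0527), 1000 g replicate 1 (0.0551) and 1000 g replicate 2 (0.0567). Cluster 12, which carried notch3 and cspg4 of the mural cells around vessels, rose from 0.674 ± 0.235% to 3.80 ± 1.35% (r = 0.86, permutation p = 3.9e-04, adjusted p = 0.00205). Its rho was 0.90 (permutation p = 1.6e-04, adjusted p = 7.56e-04), and r without the 2 farthest was 0.781 to 0.820. Clusters 20 and 23 both fell. The named genes leading cluster 20 were contractile ones such as acte1, tnni1c and tpm2. Those leading cluster 23 were tpm2, slc25a4, ndkb, myoz2b, atp5me and fbp2. Cluster 20 went from 1.01 ± 0.0929% to 0.0381 ± 0.066% (r = -0.96, permutation p = 2e-05, adjusted p = 1.4e-04), with a rho of -0.93 (permutation p = 7e-05, adjusted p = 7e-04) and an r of -0.957 to -0.929 without the 2 farthest. Cluster 23 went from 1.1 ± 0.538% to 0.0312 ± 0.0289% (r = -0.87, permutation p = 1e-05, the smallest possible, adjusted p = 1.05e-04), with a rho of -0.90 (permutation p = 2.2e-04, adjusted p = 7.7e-04) and an r of -0.956 to -0.931 without the 2 farthest. The MuSC-like share itself did not pass (r = -0.61, permutation p = 0.0403, adjusted p = 0.0605). Its rho was -0.50 (permutation p = 0.0976, adjusted p = 0.146) and r without the 2 farthest -0.430 to -0.367, although without 1500 g replicate 1 it passed (r = -0.77, adjusted p = 0.023). The B cell-like share stood at an adjusted p of 0.0577 (r = 0.59, permutation p = 0.0303), with a rho of 0.67 (p = 0.0214, adjusted p = 0.0409) and an r of 0.464 to 0.609 without the 2 farthest. It passed the permutation test without any 1 of the 1500 g libraries (adjusted p = 0.0405, 0.0364 and 0.0471 without replicates 1, 2 and 3).

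Among the classes without a call, cluster 0 went from 7.81 ± 1.44% at 10 g to 22.7 ± 2.20% at 500 g (n = 2) and back to 12.1 ± 2.27% at 1500 g (r = 0.58, permutation p = 0.0456, adjusted p = 0.0638). Erythroid-like cells stood at 6.10 ± 1.52% and 9.03 ± 2.13% (r = 0.44, permutation p = 0.152, adjusted p = 0.188). Fibroblast/FAP-like cells stood at 6.22 ± 0.753% and 7.82 ± 2.21% (r = 0.39, permutation p = 0.22, adjusted p = 0.243), glia-like cells at 4.17 ± 0.504% and 4.96 ± 1.35% (r = 0.35, p = 0.282, adjusted p = 0.296) and T/NK cell-like cells at 1.82 ± 0.465% and 1.68 ± 0.452% (r = -0.20, p = 0.523, adjusted p = 0.523). The falls of cluster 16 (r = -0.67, permutation p = 0.00803, adjusted p = 0.0222, rho = -0.76, p = 0.00647, adjusted p = 0.0151) and cluster 5 (r = -0.68, p = 0.0154, adjusted p = 0.0349, rho = -0.64, p = 0.0283, adjusted p = 0.0495) leaned on single libraries. In the permutation test cluster 16 lost its call without 10 g replicate 2 (adjusted p = 0.0504) or replicate 3 (0.105). Its r ranged from -0.821 to -0.390 without the 2 farthest libraries. Cluster 5 lost its call without 10 g replicate 2 (0.107), 10 g replicate 3 (0.0746), 1000 g replicate 1 (0.0565), 1000 g replicate 2 (0.0609) or 1500 g replicate 1 (0.0511), with an r of -0.909 to -0.456 without the 2 farthest.

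**Figure D1:**
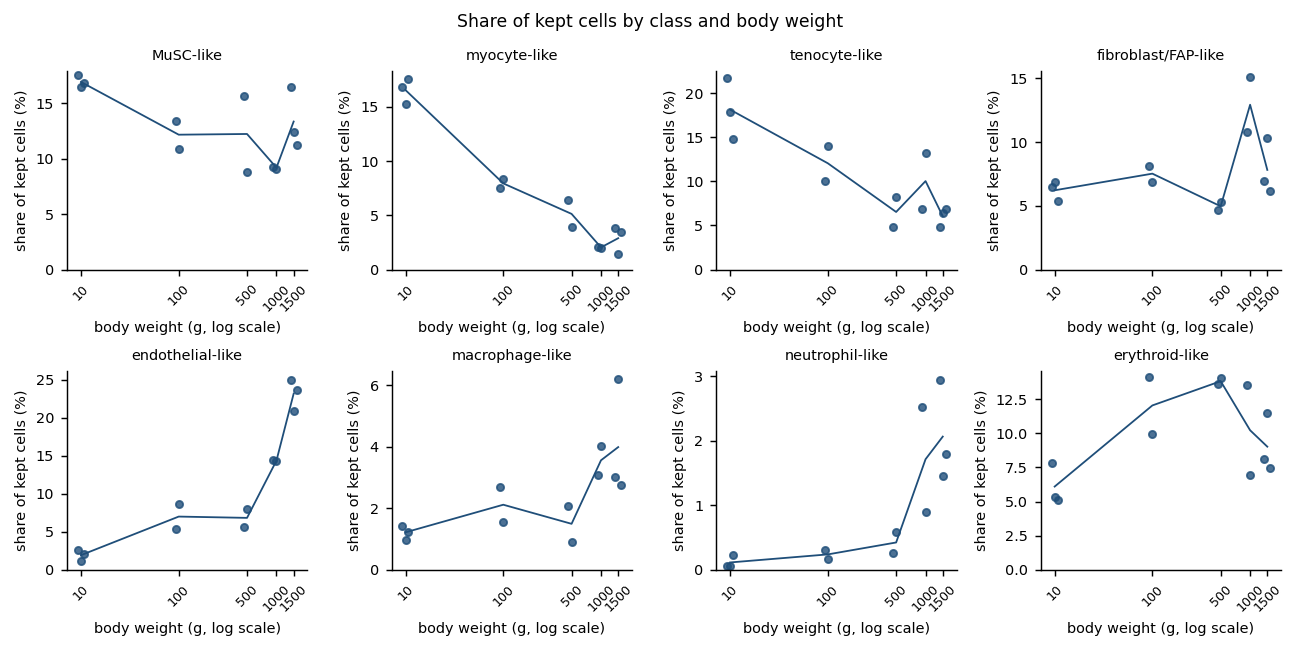
Share of the kept cells in the main classes of white muscle cells by body weight. Each point is 1 library (10 g n = 3, 100 g n = 2, 500 g n = 2, 1000 g n = 2, 1500 g n = 3) and the line joins the means.

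MuSC-like cells of the heavier fish held less of the G2/M transcripts. The summed level of the G2/M list, genes of mitosis such as mki67, top2a and smc4, was 168 ± 20.2 CPM at 10 g (n = 3), 147 at 100 g, 144 at 500 g, 43.4 at 1000 g and 65.4 ± 21.4 at 1500 g (n = 3). The share of MuSC-like cells with at least 3 G2/M UMIs, after each cell had been thinned to 2000 UMIs, went from 2.94 ± 0.240% at 10 g to 1.95%, 2.25%, 0.195% and 1.12 ± 0.431% at the 4 higher weights. Erythroid-like cells, which should not divide, gave 0.045% over all libraries when thinned in the same way. Their main cluster had a median of 18680 UMIs per cell, against 12310 and 4947 in clusters 3 and 9. The same free RNA is then a smaller part of their thinned UMIs, so that 0.045% does not bound free RNA in MuSC-like cells. Myocyte-like cells went from 18.4 ± 3.03% to 6.97 ± 2.12%. The S phase list, genes of DNA replication such as mcm3, stood at 72.6 ± 30.1 CPM at 10 g and 62.2 ± 2.70 at 1500 g.

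The log2 G2/M level fell with log10 weight (r = -0.76, permutation p = 0.00601, adjusted p = 0.012 over 2 lists). Its rho was -0.75 (permutation p = 0.00762, adjusted p = 0.0152), and r was -0.750 to -0.693 without the 2 libraries farthest from the median weight. The cycling share fell with it (r = -0.80, permutation p = 0.00248, a family of 1 relation), with a rho of -0.78 (p = 0.00398) and an r of -0.735 to -0.669 without the 2 farthest. The S phase level had r = -0.34 (permutation p = 0.291, adjusted p = 0.291) and rho = -0.07 (p = 0.825, adjusted p = 0.825), with an r of -0.750 to 0.0246 without the 2 farthest. The G2/M call was lost when the cells were clustered on expression centred within each library (r = -0.42, adjusted p = 0.348).

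**Figure D2:**
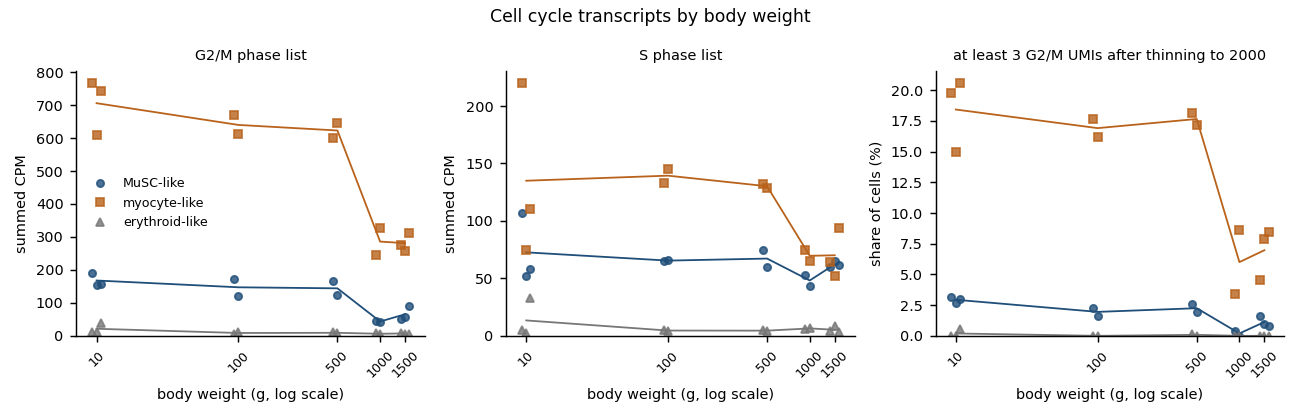
Cell cycle genes by body weight: summed CPM of the G2/M and S phase lists and the thinned share of cells with G2/M UMIs, in MuSC-like, myocyte-like and erythroid-like cells. Each point is 1 library.

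Within MuSC-like cells col5a3a, cd209 and tcf21 were among the genes that rose with body weight, epha6, kcnma1a and sox9 among those that fell, and pax7a and pax7b gave no call. The collagen gene col5a3a had 4.63 ± 2.31 CPM at 10 g and 101 ± 18.4 at 1500 g (n = 3 each), the lectin receptor gene cd209 34.0 ± 9.23 and 463 ± 119, and the mesenchymal transcription factor gene tcf21 21.5 ± 3.73 and 232 ± 127. In the other direction, epha6, an ephrin receptor, went from 35.6 ± 17.3 to 1.90 ± 1.01 CPM, the potassium channel gene kcnma1a from 153 ± 32 to 28.3 ± 9.15 and the transcription factor gene sox9 from 82.0 ± 17.7 to 26.9 ± 11.7. By contrast pax7a had 24.3 ± 0.695 CPM at 10 g and 24.4 ± 6.0 at 1500 g. Free RNA was not tested for the falls of epha6, kcnma1a and sox9, and sox9 was also a leading gene of cluster 0.

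The edgeR trend test over 12 libraries called 2090 of 22535 genes at an adjusted p under 0.05, 1402 with a positive and 688 with a negative slope. Slopes are log2 changes per 10-fold body weight with their SE. The largest slope by the rule for named genes (226 genes eligible in edgeR) was that of e1 (8.05 ± 1.70, adjusted p = 0.0165), which had 0 CPM in every 10 g and 100 g library and 3.81, 1.93 and 355 CPM at 1500 g. Its edgeR call was lost without 500 g replicate 2 or 1500 g replicate 3, and without the latter the slope was 3.29 (adjusted p = 0.11). Then came the rises of col5a3a (1.93 ± 0.19, adjusted p = 3.17e-05), cd209 (1.71 ± 0.19, 7.55e-05) and tcf21 (1.44 ± 0.24, 0.00304). They were followed by the chemokine gene il-8 (1.37 ± 0.27, 0.00831), s8 (1.36 ± 0.23, 0.00304), the calcium channel subunit gene cacng2a (1.13 ± 0.20, 0.00281) and the hyaluronan link protein gene hapln4 (1.11 ± 0.20, 0.00288). The stress-induced zinc finger gene zfand2a (1.11 ± 0.15, 1.99e-04), the small GTPase gene rab18a (1.00 ± 0.16, 0.00126), tnfsf13 of the tumour necrosis factor family (1.00 ± 0.13, 2e-04) and the deubiquitinase gene uchl1 (0.98 ± 0.15, 9.38e-04) had smaller slopes. These 11 kept their call without any 1 library. The count of called genes was 1264 without 10 g replicate 1, 1119 without 10 g replicate 3 and 1377 without 1500 g replicate 3.

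The falls (88 genes eligible) were led by epha6 (-1.22 ± 0.25, adjusted p = 0.00967 by edgeR, 12 libraries), the collagen gene col8a2 (-1.0 ± 0.14, 3.73e-04), the planar polarity cadherin gene celsr1a (-0.93 ± 0.20, 0.00942) and kcnma1a (-0.87 ± 0.13, 5.45e-04). Also among them were sox9 (-0.78 ± 0.13, 0.00196), the kinase gene map3k1 (-0.75 ± 0.13, 0.00226), cxxc5a (-0.74 ± 0.14, 0.00288) and smc4, a subunit of condensin (-0.72 ± 0.15, 0.00609). All 8 were called without any 1 library. Free RNA was not tested for these falls, apart from smc4 as a part of the G2/M list. Less secure was gfra1a, a receptor for the GDNF family (-1.07 ± 0.27, 0.0291, 103 ± 28.5 to 8.27 ± 3.34 CPM). It lost its edgeR call without 10 g replicate 2, 10 g replicate 3 or 1500 g replicate 1 (highest adjusted p = 0.0777). The call of fst, follistatin, which binds myostatin and activin (-0.78 ± 0.19, 0.0223), was lost without 10 g replicate 2 or 3 (highest 0.0902). The coagulation factor gene f8 (-0.70 ± 0.16, 0.0136) was lost without 10 g replicate 3 (0.0778), and hmgn6, a nucleosome-binding protein gene (-0.69 ± 0.19, 0.0315), without 10 g replicates 1 and 3, 1000 g replicate 1 and 1500 g replicates 1 and 3 (highest 0.104). In each gene named by the rule the 3 libraries at 1500 g lay all above or all below the 3 at 10 g, a separation that chance gives 10% of genes.

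The regulators fixed for a look whatever their result gave no call: pax7a (-0.08 ± 0.11, adjusted p = 0.73 by edgeR), pax7b (0.13 ± 0.10, 0.467), and LOC100136271, the locus matched to myf5 (0.25 ± 0.09, 0.0862). Nor were there calls for myod (-0.10 ± 0.27, 0.873), myog (-0.53 ± 0.18, 0.0732), mki67 (-0.84 ± 0.28, 0.0824) and top2a (-0.62 ± 0.19, 0.0531). LOC100136271 passed without 10 g replicate 3 (0.0428), myog without 1500 g replicate 3 (0.0333), mki67 without 500 g replicate 1 (0.0264) and top2a without 10 g replicate 2 (0.035) or 500 g replicate 1 (0.0143). With MuSC-like cells defined after centring within libraries, as clusters of 4886 and 1234 cells, the slopes of mki67 (0.07), myod (0.73), myog (1.46) and smc4 (0.03) turned positive.

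**Figure D3:**
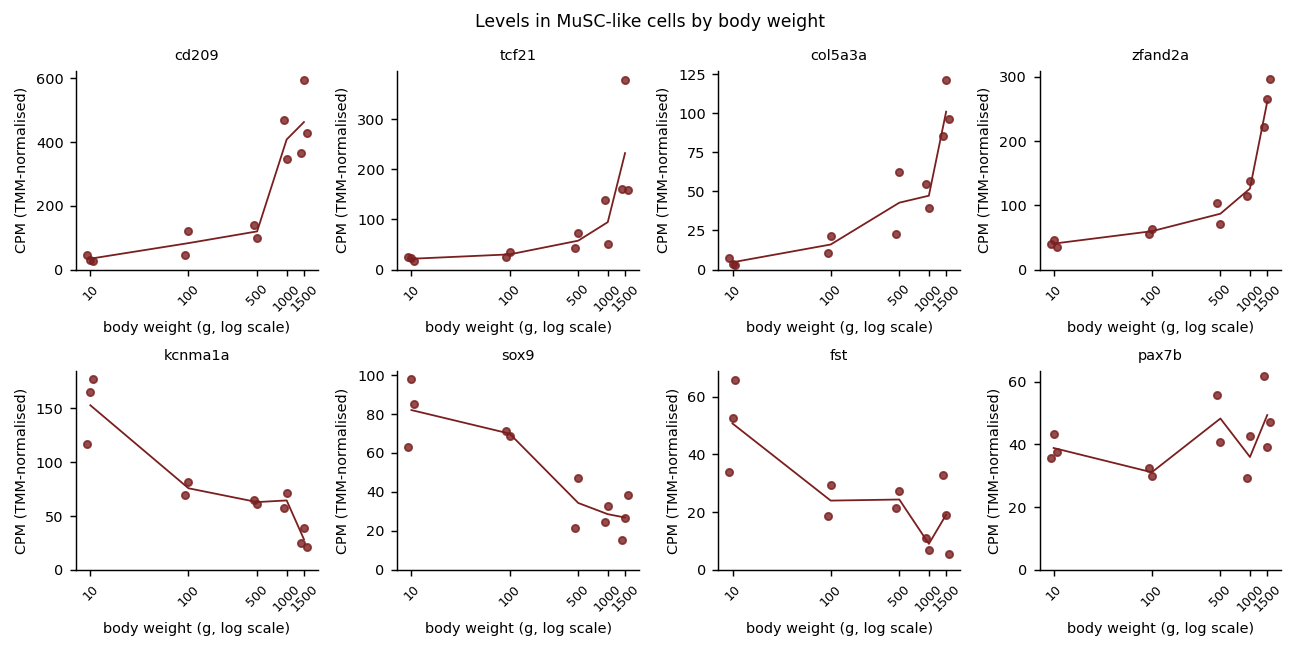
CPM of named genes in MuSC-like cells by body weight, 1 point per library (10 g n = 3, 100 g n = 2, 500 g n = 2, 1000 g n = 2, 1500 g n = 3).

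In MuSC-like cells 4 of the 15 gene lists passed camera at its preset correlation, 1 upward and 3 downward, and none passed with an estimated one. Of 18 measured immediate-early and heat-shock genes 6 rose and 0 fell (7 and 0 adjusted over the list alone, median slope 0.31). Among them were cebpb (0.66 ± 0.10, 73.2 to 211 CPM) and the chaperone gene hspa8b (0.48 ± 0.11, 66.3 to 155 CPM), both called without any 1 library. In edgeR the chaperone gene hsp70b (0.73 ± 0.20, 342 ± 178 to 1092 ± 416 CPM, adjusted p = 0.032) lost its call without 10 g replicates 2 and 3 and 1500 g replicates 1 and 3 (highest adjusted p = 0.0837). Barcodes of the 1500 g libraries also had a higher median share of mitochondrial UMIs (2.30, 2.69 and 2.28% against 1.44, 1.37 and 1.73% at 10 g). A link of that share with the stress genes was not tested. Of 13 G2/M genes 0 rose and 2 fell (0 and 8 adjusted over the list alone, median -0.72), namely smc4 and bub1bb of the spindle checkpoint (-0.85 ± 0.24, 0.032). The call of bub1bb was lost without 10 g replicate 1, either 1000 g library or 1500 g replicate 1 or 2 (highest 0.162). Of 33 genes of oxidative phosphorylation 0 rose and 3 fell (0 and 4 adjusted over the list alone, median -0.18). Among them ndufb7 and atp5fa1 lost their calls without 10 g replicate 1 (0.183 and 0.221) and without most of the other libraries. Of 9 contractile fibre genes 0 rose and 1 fell (0 and 5 adjusted over the list alone, median -0.53), the calcium pump gene atp2a1 (-0.94 ± 0.20, 5.71 to 1.52 CPM). Its edgeR adjusted p was 0.00877, and 0.0659 without 10 g replicate 2. The fibre parvalbumin gene pvalb2 also fell in erythroid-like cells, which do not make it (-1.40, edgeR adjusted p = 0.0195, and 0.083 without 10 g replicate 3).

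Against the other genes, limma's camera called those 4 lists over 12 libraries: immediate-early and heat-shock (adjusted p = 3.67e-06), G2/M (3.78e-05), oxidative phosphorylation (0.00186) and contractile fibre (0.00695). With an estimated correlation their adjusted p-values were 0.291, 0.436, 0.655 and 0.461. No call of camera, here or in fibroblast/FAP-like cells, held with an estimated correlation. The contractile call of camera (limma) was lost without 10 g replicate 2 (adjusted p = 0.0658) and the oxidative one without 10 g replicate 1 (0.0766). Fry, which asks if a list moved as a whole, called the stress list (0.00885), G2/M (0.0373) and also glycolysis (0.00885).

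The other lists gave no camera call in MuSC-like cells. Notch pathway genes had 3 rises of 8 and 0 falls (3 and 0 adjusted over the list alone, median 0.13, limma camera adjusted p = 0.09). They were the receptor gene notch3 (0.41, 55.7 to 105 CPM), the glycosyltransferase gene lfng (0.60, 10.4 to 30.2 CPM) and the ligand gene jag1b (0.50). Each lost its edgeR call without 10 g replicate 3 or 1500 g replicate 3. Notch3 lost it also without 10 g replicate 1 or 1500 g replicate 1, lfng without 10 g replicate 2 or 1500 g replicate 1, and jag1b without 10 g replicate 1 or 1500 g replicate 2 (highest edgeR adjusted p = 0.0649, 0.0807 and 0.103). Of 20 extracellular matrix genes 1 rose, the laminin gene lama2 (0.69 ± 0.13, 51.1 to 150 CPM), and 0 fell (1 and 0 adjusted over the list alone, median 0.11, 0.09). Of 20 genes of IGF, TGF-beta and myostatin signalling 1 rose and 4 fell (1 and 4 adjusted over the list alone, median 0.01, mean -0.06, camera direction down, 0.354). The binding protein gene igfbp6b rose (0.86 ± 0.16, 3.77 to 16.7 CPM), and tgfb2 (-0.65 ± 0.15, 104 to 36.7 CPM) and the IGF receptor gene igf1ra (-0.44 ± 0.10, 89.8 to 41.7 CPM) fell, all 3 called without any 1 library. Of 9 adipogenic and lipid genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.06, 0.09), with the desaturase gene scdb (0.74 ± 0.16, 4.47 to 15.8 CPM) called without any 1 library. Glycolysis had 1 rise of 13 (3 adjusted over the list alone, limma camera adjusted p = 0.0741). Interferon response had 1 of 11 (1 adjusted over the list alone, median -0.01, mean 0.19, 0.257), in the proteasome gene psmb8a (1.16 ± 0.21). ER protein folding had 1 of 7 (1 adjusted over the list alone, 0.0997) and the quiescence-associated list 1 of 9 (1 adjusted over the list alone, 0.402). The S phase list had 1 fall of 6 (1 adjusted over the list alone, 0.826), in mcm3 (-0.44, edgeR 0.0455). That call was lost without any 1 library except 10 g replicate 2 (highest 0.281). The 12 genes of myogenic regulation and fusion (median 0.03, mean -0.01; 0.861) and the 36 ribosomal protein genes (median 0.05; 0.426) held 0 calls by edgeR.

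Among the 11 cell type lists with enough genes in MuSC-like cells, camera called the fibroblast/FAP markers upward (2 rises of 9, 2 adjusted over the list alone, median 0.22, limma adjusted p = 0.0444). The adjusted p was 0.425 with an estimated correlation, and mfap5 (199 to 646 CPM) and pdgfra (14.8 to 35.5 CPM) were called. It called the 2 skeletogenic markers downward (1 fall, 2 adjusted over the list alone, median -0.75, limma adjusted p = 0.0444), sox9 being the gene that fell. With an estimated correlation that adjusted p was 0.425 too. The 8 MuSC markers held 2 falls (1 rise and 2 falls adjusted over the list alone, 0.969), in megf10 (-0.35, 157 to 87.5 CPM) and the growth factor receptor gene fgfr4 (-0.38, 178 to 103 CPM). The myocyte (6 genes) and glia (3 genes) lists each stood at 0.185, and the tenocyte, endothelial, mural, erythroid, thrombocyte and adipocyte lists at 0.969, the tenocyte list with 1 rise, in thbs4a (1.40), and the mural list with notch3.

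**Figure D4:**
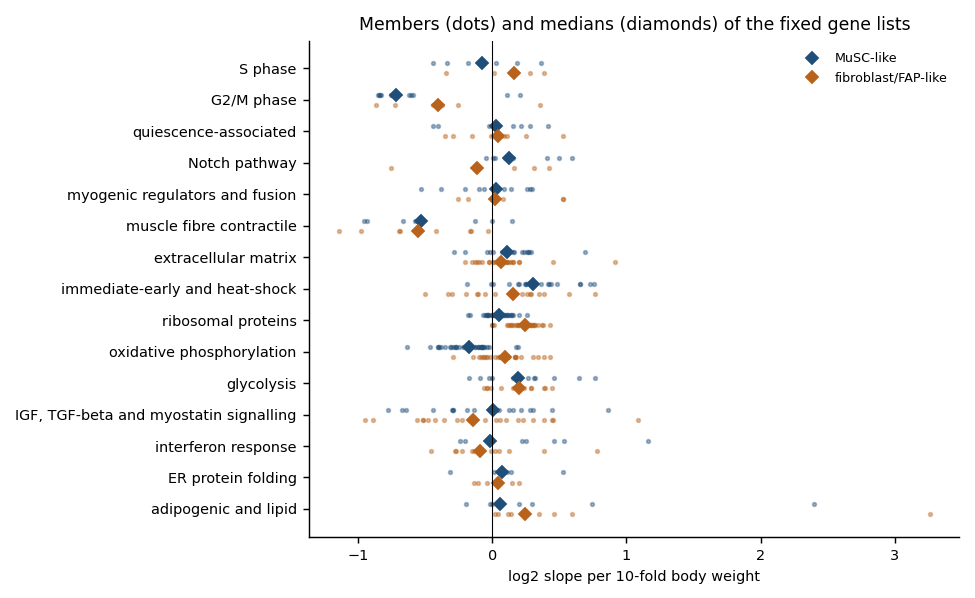
Slopes with body weight of the members of each gene list, as dots, and their medians, as diamonds, in MuSC-like and fibroblast/FAP-like cells.

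Few genes were called in MuSC-like cells at 100 g. Against 10 g, edgeR called 44 of 24550 genes at 100 g (24 higher, 20 lower), 1282 at 500 g (819 higher, 463 lower), 1466 at 1000 g (765 higher, 701 lower) and 3611 at 1500 g (2075 higher, 1536 lower). The lower weights rest on 2 libraries each, and their counts ran from 0 to 262, 201 to 1518 and 382 to 1580 as single libraries were left out. At 1500 g the count fell to 2157 without 10 g replicate 3 and to 2213 without 1500 g replicate 3. With cells clustered after centring within libraries, 1447 genes were higher and 1644 lower at 500 g. Without the filter on low counts 765 genes were called at 100 g (279 higher, 486 lower), and in cluster 3 alone 425 at 500 g. The class was also made up differently: cluster 9 held 281, 193 and 187 cells in the 10 g libraries against 671, 442 and 383 of cluster 3, and at 500 g 347 and 215 against 360 and 192.

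In fibroblast/FAP-like cells apoe, c4b and fbln1 were among the genes that rose and lpar3 and gem among those that fell, apoe and lpar3 less securely. The apolipoprotein gene apoe had 1.59 ± 1.89 CPM at 10 g and 85.8 ± 88.2 at 1500 g (n = 3 each), the complement gene c4b 1.51 and 26.7, and fbln1, a matrix fibulin, 3.93 ± 3.63 and 92.9 ± 40.6. The lysophosphatidic acid receptor gene lpar3 went from 36.5 to 1.78 CPM, and gem, a small GTPase gene, from 77.7 to 12.1. The markers cd209 (0.52, 459 to 1107 CPM) and tcf21 (1.11, 128 to 802 CPM) rose here as well. The make-up of the class also differed: cluster 17, in which fbln1 stood at 136 CPM against 14.7 in cluster 7, held 46, 20 and 22 cells at 10 g against 304, 244 and 160 of cluster 7, and 21, 24 and 62 at 1500 g against 59, 259 and 155.

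The edgeR trend over 12 libraries called 1049 of 18679 genes, 532 with a positive and 517 with a negative slope, and the comparison of 1500 g with 10 g called 1733 of 20674 (932 higher, 801 lower). By edgeR, of the rises that the rule picked (95 eligible), those of c4b (1.94 ± 0.29, adjusted p = 0.00118), fbln1 (1.85 ± 0.24, 4.6e-04), shbgb (1.59 ± 0.24, 0.00144), m1ip1 (1.27, 0.0111) and id2, an inhibitor of helix-loop-helix factors (1.26 ± 0.16, 3.09e-04), were called without any 1 library. So were the falls (74 eligible) of stard13a (-1.11, 0.00195), ccbe1 (-1.07, 0.0014), cilp (-1.04, 0.00471), fam102ab (-1.01, 0.00104) and gem (-1.0, 0.00104). Free RNA was not tested for these falls. The calls of apoe (3.26 ± 0.73, 0.0197) and lpar3 (-1.42 ± 0.31, 0.0146) were lost without 10 g replicate 2 (0.0744 and 0.0565). Those of myoc (1.57, 0.0235) and pvalb2 (-1.14 ± 0.24, 0.0135) were lost without 10 g replicate 2 or 3 (highest 0.0653 and 0.068). The call of s100b (1.67 ± 0.42, 0.0344) was lost without either 100 g library, 10 g replicates 2 and 3 or 1500 g replicates 1 and 3 (highest 0.121). That of vwde (-1.16 ± 0.29, 0.0349) was lost without 10 g replicates 1 and 3, 1000 g replicate 1 or 1500 g replicates 1 and 3 (highest 0.0732). The trend count was 588 without 10 g replicate 2 and 510 without 10 g replicate 3. The count at 1500 g was 2876, 873, 785 and 963 without 10 g replicates 1, 2 and 3 and 1500 g replicate 3. The class changed with the processing. With stricter cell filters the class was drawn from clusters of 5020 and 496 cells, and without doublet removal from clusters of 5304 and 515. Of the 1049 genes 421 and 402 were then called again, and gem had a slope of 0.15 without doublet removal.

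In fibroblast/FAP-like cells 4 lists passed camera at its preset correlation, and none passed with an estimated one or by fry. Of 8 adipogenic and lipid genes 2 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.24, limma camera adjusted p = 0.00708). With an estimated correlation the adjusted p was 0.36. The genes that rose were apoe and scdb (0.60, edgeR 0.0146, and 0.072 without 10 g replicate 2). Of 36 ribosomal protein genes 0 were called (0 adjusted over the list alone), but 35 had a positive slope (median 0.24, limma camera adjusted p = 1.68e-06). With an estimated correlation the adjusted p was 0.766. Of 8 contractile fibre genes 0 rose and 2 fell (0 and 4 adjusted over the list alone, median -0.55, camera 0.00133), and the adjusted p was 0.36 with an estimated correlation. They were pvalb2 and atp2a1 (-0.98, edgeR 0.0256, lost without 10 g replicates 2 and 3, 1000 g replicate 2 and 1500 g replicate 2, highest 0.19). Of 6 G2/M genes 0 rose and 1 fell (1 and 4 adjusted over the list alone, median -0.41, camera 0.0411), again with an adjusted p of 0.36 with an estimated correlation. The kinesin gene cenpe fell (-0.87, edgeR 0.0326, lost without 10 g replicates 1, 2 and 3, 1000 g replicate 1 or 1500 g replicate 2, highest 0.135). The camera call of this list was lost without 6 libraries (adjusted p from 0.0546 to 0.126). Fry called none of the 15 lists in this class, the lowest adjusted p being 0.0501 for G2/M and for the adipogenic list.

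No other list passed camera in fibroblast/FAP-like cells. Of 24 genes of IGF, TGF-beta and myostatin signalling 2 rose and 2 fell (4 and 6 adjusted over the list alone, limma camera adjusted p = 0.538). The binding protein gene igfbp3 (1.09 ± 0.18, 2.69 to 15.9 CPM) kept its rise without any 1 library. By edgeR, id3 (0.45, 0.041), bmp1a (-0.51, 0.0323) and igf1ra (-0.48, 0.0347, 70.1 to 27.3 CPM) lost their calls without 7, 7 and 5 libraries (highest 0.147, 0.11 and 0.12). Of 18 stress genes 1 rose and 1 fell (2 and 1 adjusted over the list alone, camera 0.438). Of 13 interferon genes 1 rose, psmb8a, and 1 fell, irf9 (1 and 3 adjusted over the list alone, 0.438). Of 22 matrix genes 1 rose, sparc (1 adjusted over the list alone, 0.687), and of 13 glycolysis genes 1 rose, pgk1 (1 adjusted over the list alone, 0.136). The calls of sparc and pgk1 were lost without 4 and 5 libraries (highest edgeR adjusted p = 0.161 and 0.113, without 10 g libraries). Of 7 Notch genes 1 fell, lfng (-0.75 ± 0.17, 38.5 to 17 CPM, 1 adjusted over the list alone, camera 0.754). The edgeR calls of lfng, irf9 and psmb8a were each lost without 1 library (0.0863 without 10 g replicate 1, 0.0786 without 10 g replicate 3 and 0.0639 without 10 g replicate 2). Oxidative phosphorylation (32 genes, 0.136), S phase (5 genes, 0.438), ER protein folding (7 genes, 0.489), myogenic regulation (8 genes, 0.593) and the quiescence-associated list (8 genes, 0.841) held 0 edgeR calls. None of 9 cell type lists passed camera (limma), the lowest adjusted p being 0.471 for the fibroblast/FAP and adipocyte markers (tenocyte 0.791, endothelial 0.704, mural and skeletogenic 0.904, MuSC, myocyte and thrombocyte 0.815).

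The difference between both classes was tested in a fit with the library as a block. EdgeR called 1492 of 18359 genes, 903 with the higher slope in MuSC-like cells and 589 with the lower. Most of the 346 genes called in both classes moved the same way. Both classes shared 230 rises and 107 falls, where independent lists would share 28.7 and 14.5. Only 9 genes ran in opposite directions with a called difference. Of these 5 rose in MuSC-like cells and 4 fell, against 30.1 and 13.8 for independent lists. Both classes come from the same libraries, and the cause of the agreement was not tested. The filament gene vim went from 210 to 145 CPM in MuSC-like cells and from 9.67 to 55.6 in fibroblast/FAP-like cells (difference of slopes -1.40, edgeR adjusted p = 1.29e-06). The gene lfng went from 10.4 to 30.2 and from 38.5 to 17 (1.30, 1.73e-06), although its fibroblast/FAP-like slope was positive under 3 alternatives (0.030, 0.033 and 0.18). The gene egln2, an oxygen sensor, went from 11.8 to 6.61 and from 2.42 to 8.28 (-1.21, 2.45e-04). In MuSC-like cells alone the edgeR adjusted p was 0.0458 for vim and 0.0328 for egln2, and neither gene was tested again under the alternatives. The count was 755 without 10 g replicate 2 and 618 without 10 g replicate 3.

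Every other class with enough cells held genes called with weight, some of them shared between classes. No share of free RNA was taken off in these tests, and falls of transcripts of tendon, connective tissue, fibre and dividing cells outside the cells that lead in them are therefore left out of this part. In endothelial-like cells (1961 genes called by edgeR, 1069 up) the stress genes zfand2a (1.39, adjusted p = 2.18e-04, 59.9 to 554 CPM) and hsp70b (1.36, 0.00937, 286 to 2641 CPM) and the gene mustn1b (1.14, 0.00769) rose. Without doublet removal the slope of mustn1b was -0.14. This class joins clusters 6 and 10, and its make-up differed between weights. Cluster 10 held 44, 22 and 30 cells in the 10 g libraries against 95, 22 and 41 of cluster 6. At 1500 g it held 65, 102 and 149 against 224, 471 and 680. In myocyte-like cells (698 called, 505 up) znf804a (1.76, 0.00386, 4.78 to 102 CPM) and keap1a, a sensor of oxidative stress (1.33, 0.00446), rose, and the histone methyltransferase gene kmt5ab (-0.80, 0.0102) fell. In tenocyte-like cells (1571 called, 876 up) cd209 (1.95, 0.00163, 18.1 to 413 CPM) and prex2 (1.58, 2.18e-05) rose and the matrix gene tnn (-1.44, 0.00153) fell. In glia-like cells (1502 called, 931 up) the adhesion gene vcam1b (1.86, 2.91e-04, 14.9 to 174 CPM) and rsph1 (1.34, 4.2e-04) rose. The hedgehog ligand gene dhh (-1.26, 0.0029, 37.7 to 2.17 CPM) and rasgef1bb (-1.0, 5.31e-04) fell.

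Among blood and immune cells, erythroid-like cells (780 called, 351 up) gained vig1, an interferon-induced antiviral gene (1.20, edgeR adjusted p = 0.00214, 26.3 to 112 CPM), and socs1, a brake on cytokine signalling (1.14, 4.43e-04). The class joins cluster 2 and cluster 21, the latter led by vig1 and ifit9, and its make-up differed between weights: cluster 21 had 0, 0 and 2 cells in the 10 g libraries, 82 and 88 at 500 g and 3, 7 and 7 at 1500 g. Macrophage-like cells (200 called, 59 up) gained rnf11b (1.23, 0.00791) and lost bcl3 of NF-kappaB signalling (-1.25, 0.00214, 90.3 to 9.56 CPM) and rgl1 (-1.20, 5.47e-04). T/NK cell-like cells (139 called, 71 up, 11 libraries) lost the integrin gene itgb7 (-1.36, 0.00545, 89.0 to 8.27 CPM) and b4galnt4a (-1.73, 7.76e-04), and B cell-like cells (6 called, 4 up, 11 libraries) gained gnao1a (1.54, 0.00347, 12.8 to 92.5 CPM).

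Of the clusters without a name, cluster 0 (2336 called by edgeR, 1418 up) gained il-8 (1.59, adjusted p = 4.14e-06, 7.28 to 74.9 CPM), sulf1 (1.61, 1.27e-05) and tafa5a (2.68, 2.77e-04). Cluster 12 (113 called, 79 up, 11 libraries) gained eppk1 (2.66, 2.85e-05, 4.35 to 120 CPM) and plk2b (2.69, 0.0071). Cluster 15, which carried foxd3 and cdh19 (1166 called, 615 up, 11 libraries), gained the chemokine gene ccl44 (2.99, 2.8e-05), adamts8a (1.65, 0.00428) and the co-chaperone gene bag3 (1.47, 2.54e-04, 38.0 to 359 CPM) and lost aopep (-1.17, 2.43e-04). Cluster 5, the cells with fibre transcripts (756 called, 356 up), gained ppdpfa (2.16, 2.96e-07, 34.9 to 952 CPM) and pdlim5a (1.56, 1.94e-05). It lost ndkb (-1.71, 6.67e-04), pvalb2 (-1.09, 9.32e-06, 36471 to 7340 CPM) and ntmt1 (-0.89, 0.00126).

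The genes named in these other classes kept their call in every fit that left out 1 library and still tested them. Of the 11 such fits in each class, plk2b in cluster 12 was tested in only 5 and adamts8a in cluster 15 in only 7. Both calls are therefore less secure. The rule picked another 23 genes that lost theirs in at least 1 such fit: 4 in T/NK cell-like, 3 each in macrophage-like, tenocyte-like and cluster 12 cells, 2 each in erythroid-like, myocyte-like and cluster 15 cells, and 1 each in glia-like, B cell-like, cluster 0 and cluster 5 cells; their values are not given here. Counts of called genes moved with single libraries too, from 2 to 11 in B cell-like, 46 to 130 in T/NK cell-like, 80 to 258 in macrophage-like, 36 to 160 in cluster 12, 293 to 798 in myocyte-like, 732 to 1507 in glia-like, 1038 to 2273 in endothelial-like, 468 to 854 in erythroid-like, 974 to 1677 in tenocyte-like, 653 to 1135 in cluster 15 and 473 to 747 in cluster 5 cells.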

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

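The tests of the G2/M pattern, of the free RNA of muscle fibres and of fibroblast/FAP-like cells by ngfa were chosen only after the result was seen; the other tests here were set before. The difference of trends between MuSC-like and fibroblast/FAP-like cells stands out because the class by weight term itself was called, by edgeR, for 1492 genes. Most of the 346 genes called in both classes nevertheless moved the same way, 230 up and 107 down. Another 9 had opposite trends with a called difference. The 3 of them with a gene name were vim (-1.40), lfng (1.30) and egln2 (-1.21, slope in MuSC-like less that in fibroblast/FAP-like cells). The sign of lfng in fibroblast/FAP-like cells turned under 3 alternatives (slopes 0.030, 0.033 and 0.18), so its place here depends on the processing.

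The genes cd209 and tcf21, leading genes of the fibroblast/FAP-like class, rose with weight in MuSC-like cells. Free RNA in all droplets is argued against by erythroid-like cells of the 1500 g libraries, which held 0.0137 of the MuSC-like CPM (median over the libraries, for the higher of both genes). Fibroblast/FAP-like cells among the MuSC-like ones are a possible explanation by pdgfra, which allowed up to 2.67 times the share that cd209 would need, but pdgfra did not separate both classes at 1500 g (23.4 to 37.1 CPM in MuSC-like and 35.0 to 45.9 in fibroblast/FAP-like cells). The gene ngfa, which does separate them, allowed at most 0.024 of the needed share (0.509 to 0.726% against 30.3 to 52.1%), a test picked after pdgfra had failed to decide. A change within MuSC-like cells stays open and untested.

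By camera at its preset correlation, contractile fibre transcripts fell with weight in MuSC-like and fibroblast/FAP-like cells. Neither call held with an estimated correlation or by fry. Free fibre RNA shared by all droplets is a candidate explanation: the list's summed level in MuSC-like cells followed that in erythroid-like cells over the 12 libraries (r = 0.898, permutation p = 5e-05; rho = 0.888, p = 2.5e-04; r = 0.795 without the 2 libraries farthest from the median MuSC-like level of the list), and at 10 g erythroid-like cells held a median of 0.559 of the MuSC-like level (384 of 686, 610 of 1469 and 728 of 749 CPM), with the second library under the 0.5 that was asked for. A loss within MuSC-like cells alone was not shown. The difference of both levels had r = -0.204 with log10 weight (permutation p = 0.518, and rho = -0.43, p = 0.163). The erythroid-like level itself was not tested against weight. A loss of the MuSC-like cells' own stays open, since a p of 0.518 does not show that there was none.

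The G2/M list fell with weight in MuSC-like cells. Free RNA of dividing cells cannot be told apart as a part of the level. Erythroid-like cells held up to 0.252 of the MuSC-like level in 1 of the 10 g libraries. After taking off the erythroid-like level the fall remained (r = -0.723, permutation p = 0.00995, and rho = -0.745, p = 0.00751). This does not settle whether free RNA made the whole fall. The main erythroid-like cluster had a median of 18680 UMIs per cell, against 12310 and 4947 in clusters 3 and 9. The same free RNA is a smaller CPM in such cells, so that too little may have been taken off. Of myocyte-like cells among the MuSC-like ones, myog allowed at most 0.153 of the share needed for the whole 10 g level (3.25 to 3.58% against 21.3 to 25.4%). This argues against myocyte-like cells of average make-up as the source of that whole level. Dividing cells low in myog, or a smaller share behind the fall alone, are not bounded by it. Lower depth per cell is argued against by the thinned share, which still fell (permutation p = 0.00248). Fewer dividing MuSC-like cells in heavier fish may be the reason, as a hypothesis found and tested on the same data, and the fall was not called after centring within libraries.

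Chance alone is unlikely for both trends: of 100 regroupings of the libraries, 1, the real one, called as many genes in MuSC-like cells (2090, highest other 616) and 1 in fibroblast/FAP-like cells (1049, highest other 89). The real grouping is itself 1 of the 100, so that chance is not excluded. Regrouping also does not separate weight from depth. For 1500 g against 10 g the 10 splits are too few for a share under 0.05, with 3611 real and at most 0 other calls in MuSC-like cells and 1733 and 5 in fibroblast/FAP-like cells, the real split being 1 of the 10 in each case.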

How the results depend on the processing

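The single clusters, the clusters joined and the denominator without fibre-like clusters were chosen after seeing the data; the other alternatives were planned. Where a value differs, the cause was not tested. Of the alternatives other than left-out libraries, the named genes kept direction and call in 954 cases, lost the call in 176, gained one in 13 and reversed in 18. Gene lists kept theirs in 103 cases, lost 14, gained 1 and reversed 2, and shares kept theirs in 120, lost 1 (cluster 16 with the replicate block, r = -0.69, permutation adjusted p = 0.0869), gained 12 and reversed 1. The cycling share and the myocyte-like share of myogenic cells kept theirs under all alternatives run (8 and 7). Libraries of the same replicate number did not deviate together (median correlation of deviations within a number -0.0377 in MuSC-like and -0.00886 in fibroblast/FAP-like cells, against 0.00255 and 0.00434 between numbers). At weights with 2 libraries their deviations mirror each other, so that this check is weak and cannot show that no libraries were paired. With the replicate number as a block, 1581 genes were called in the MuSC-like trend, 3024 at 1500 g, 875 and 1344 in fibroblast/FAP-like cells and 1177 in the trend difference. Depth fell with weight and was not separated from it; equal numbers of cells and thinned cells address only the numbers of cells and the UMIs per cell.

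The main fits called 2090 (MuSC-like trend), 3611 (1500 g), 44, 1282 and 1466 (100 g, 500 g and 1000 g), 1049 (fibroblast/FAP-like trend), 1733 (1500 g) and 1492 genes (trend difference), with 6 in B cell-like, 780 in erythroid-like, 139 in T/NK cell-like and 200 in macrophage-like cells and 113 in cluster 12. Counts that moved by more than 1.5-fold were the following, with the split of higher and lower calls where centring, the low-count filter or single clusters moved it most. DESeq2 as test: 1668 in the fibroblast/FAP-like trend. Leiden resolution 1.0: 469 there and 978 at 1500 g. Strict cell filter: 1805. No doublet removal: 1898, with 22 in B cell-like and 2012 in erythroid-like cells. Equal cells: MuSC-like trend 1111, 1500 g 1882, 1000 g 686, 500 g 406 and 100 g 10, and fibroblast/FAP-like trend 437 and 1500 g 699. Centred within libraries: MuSC-like trend 1045 and 500 g 3091 (1447 higher, 1644 lower, against 819 and 463). No low-count filter: 100 g 765 (279 higher, 486 lower, against 24 and 20), 500 g 2845 (1398 higher, 1447 lower), 1000 g 2587, fibroblast/FAP-like 1500 g 2779, and 124 in B cell-like, 550 in T/NK cell-like, 437 in cluster 12 and 365 in macrophage-like cells. Replicate block: 100 g 14, 500 g 734 and 1000 g 941. Cluster 3 alone: 100 g 25 and 500 g 425 (315 higher, 110 lower). Cluster 9 alone: 500 g 567, 1000 g 932 and 1500 g 1116, with a trend of 941 higher and 734 lower (main 1402 and 688). Cluster 17 alone: fibroblast/FAP-like trend 250 and 1500 g 315. The other alternatives stayed within 1.5-fold: 9 each for the MuSC-like trend and 1500 g, 6 and 8 for the fibroblast/FAP-like ones, 16 for the middle weights, 38 for the other classes and 3 for the trend difference.

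Shares and levels (adjusted p by permutation): without erythroid-like cells in the denominator B cell-like passed (r = 0.62, p = 0.0396), and without clusters 5, 20 and 23 too MuSC-like passed (-0.69, 0.042). With log2 odds (0.66, 0.0256), centring (0.60, 0.0499), no cell filter (0.58, 0.0445) or the block (0.77, 0.0447) B cell-like passed. With no cell filter MuSC-like (-0.66, 0.0379) and fibroblast/FAP-like (0.66, 0.0369) passed, the latter also without doublet removal (0.67, 0.0306). With the strict filter the erythroid-like r turned (-0.034, permutation p = 0.912). Centred, the G2/M level was lost (-0.42, 0.348), and with myocyte-like cells added the S phase level passed (-0.58, 0.0463).

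Lists (adjusted p): with an estimated correlation all 8 camera calls were lost: in MuSC-like cells G2/M 0.436, stress 0.291, contractile 0.461 and oxidative 0.655, and in fibroblast/FAP-like cells G2/M 0.36, adipogenic 0.36, contractile 0.36 and ribosomal 0.766. With fry the contractile (0.103) and oxidative (0.269) lists were lost and glycolysis gained (0.00885) in MuSC-like cells, where the myogenic list turned (0.949), and G2/M (0.0501), adipogenic (0.0501), contractile (0.0783) and ribosomal (0.241) were lost in fibroblast/FAP-like cells. The myogenic list turned there with the block (0.834).

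Slopes that reversed: strict filter, egr1 0.11, lfng 0.030 and myod 0.051; no doublet removal, egr1 0.070, gem 0.15, lfng 0.033 and mustn1b -0.14; centred, egr1 0.18, lfng 0.18, mki67 0.069, myod 0.73, myog 1.46 and smc4 0.032; cluster 3 alone, pax7a 0.10; cluster 9 alone, fst 0.16 and pax7b -0.051; cluster 17 alone, id3 -0.23 and pgk1 -0.22. Here egr1, gem, lfng, id3 and pgk1 are those of fibroblast/FAP-like, mustn1b of endothelial-like and the rest of MuSC-like cells.

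With each library left out in turn, the counts ranged as follows: MuSC-like trend 1119 to 2140, 1500 g 2157 to 3638, 100 g 0 to 262, 500 g 201 to 1518 and 1000 g 382 to 1580. Fibroblast/FAP-like trend 510 to 1169, 1500 g 785 to 2876, and trend difference 618 to 1689. Other classes: B cell-like 2 to 11, endothelial-like 1038 to 2273, erythroid-like 468 to 854, glia-like 732 to 1507, macrophage-like 80 to 258, myocyte-like 293 to 798, T/NK cell-like 46 to 130, tenocyte-like 974 to 1677, cluster 0 1651 to 2356, cluster 5 473 to 747, cluster 12 36 to 160, cluster 15 653 to 1135. The r of the shares ranged as follows: B cell-like 0.50 to 0.66, MuSC-like -0.77 to -0.52, T/NK cell-like -0.37 to 0.0054, macrophage-like 0.61 to 0.75, fibroblast/FAP-like 0.31 to 0.46, erythroid-like 0.30 to 0.54. The r of the S phase level ranged from -0.54 to 0.038 and of G2/M from -0.83 to -0.71, of the cycling share from -0.87 to -0.75, and the slope of myod from -0.32 to 0.15. The limma camera adjusted p of the lists in MuSC-like cells ranged as follows: G2/M phase 9.6e-06 to 8.57e-04, stress 1.45e-06 to 5.02e-05, contractile 0.00186 to 0.0658, oxidative 8.96e-06 to 0.0766, glycolysis 0.0171 to 0.136, Notch 0.0344 to 0.127, matrix 0.0228 to 0.362, ER folding 0.0011 to 0.478, S phase 0.419 to 0.836, myogenic 0.554 to 0.999, ribosomal 0.094 to 0.97. In fibroblast/FAP-like cells by limma: ribosomal 1.44e-08 to 0.00121, adipogenic 0.00357 to 0.0158, contractile 3.74e-04 to 0.0108, G2/M phase 0.00451 to 0.126, glycolysis 0.0297 to 0.378, oxidative 9.5e-04 to 0.972, ER folding 0.0162 to 0.959, matrix 0.317 to 0.967, quiescence 0.79 to 0.995. Of the named genes 1554 cases kept their call, 239 lost it, 5 gained one and 1 turned. Of the list tests 332 kept theirs, 8 lost it, 9 gained one and 11 turned.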

Other observations

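The comparisons across classes given here, and the tests behind them, were looked at only after the results had been seen. The genes zfand2a and hsp70b rose in several classes and were not called in others. The gene zfand2a, induced by heat and arsenite, rose by edgeR in fibroblast/FAP-like (1.18, adjusted p = 0.00154, 28.6 to 208 CPM), tenocyte-like (0.96, 5.1e-04), myocyte-like (1.08, 0.017), glia-like (0.58, 0.00388) and macrophage-like cells (0.61, 0.0428) and in clusters 0 (1.01, 0.0197) and 15 (0.98, 8.31e-04), besides MuSC-like and endothelial-like cells. It gave no call in erythroid-like cells (-0.30, 0.287), B cell-like (0.30, 0.831) or T/NK cell-like cells (0.32, 0.782) or in clusters 5 (0.58, 0.0991) and 12 (0.74, 0.0575). The chaperone gene hsp70b rose in glia-like (1.29, 0.0156) and tenocyte-like cells (0.66, 0.0208) and clusters 0 (0.92, 0.0283) and 5 (1.22, 0.0185), besides MuSC-like and endothelial-like cells. It was called in no other class, with -0.14 (0.756) in erythroid-like cells. All cells had been kept overnight in the cold, and no cause was tested.

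The division genes mki67 and top2a, not called in MuSC-like cells, fell in myocyte-like cells. By edgeR mki67 had a slope of -0.51 there (adjusted p = 0.0162, 152 CPM at 10 g) and top2a of -0.54 (0.0391). The falling slopes in MuSC-like cells, given above, were no smaller in size. A difference between both classes was not tested. Cells that do not lead in these genes had falls too, mki67 in cluster 0 (-1.69, 0.0101) and tenocyte-like cells (-1.23, 0.00404) and top2a in endothelial-like cells (-1.26, 0.0226). The values of mki67 in T/NK cell-like cells (-0.23, 0.919) and glia-like cells (-0.07, 0.957) did not pass. The summed G2/M level of myocyte-like cells was 706 ± 84.4 CPM at 10 g and 281 ± 28.2 at 1500 g (n = 3 each). The matrix gene vwde fell in tenocyte-like cells (-0.88, 0.0121) and cluster 0 (-0.97, 0.0151), besides fibroblast/FAP-like cells, and also in glia-like cells (-1.12, 0.00283), cluster 12 (-1.28, 0.0187) and erythroid-like cells (-1.38, 0.00375). No share of free RNA was taken off for any of these genes. Without single libraries the calls of mki67 in cluster 0 and of vwde in glia-like cells held, that of vwde in cluster 12 did not, and the others in this paragraph were not tested again, apart from fibroblast/FAP-like cells.

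Clusters 18, 22 and 24 had too few libraries with 20 cells for tests of genes, and cluster 16 too few at 1500 g (7, 10 and 24 cells). The r of the first 3 shares did not pass after adjustment. Cluster 18, led by egfl6 and vwde, stood at 0.88 ± 0.238% at 10 g and 0.331 ± 0.251% at 1500 g (n = 3 each; permutation p = 0.0348, adjusted p = 0.0577), but its rho passed (-0.69, permutation p = 0.017, adjusted p = 0.0357). Cluster 22, with itga2b and gp1bb of thrombocytes, stood at 0.0984 ± 0.0269% and 0.347 ± 0.153% (permutation p = 0.049, adjusted p = 0.0643). Cluster 24, with cd74b and tyrobp, had 73 cells (permutation p = 0.0357, adjusted p = 0.0577), 35 of them in 1 library. The share of cluster 15 had r = 0.41 (permutation p = 0.19, adjusted p = 0.222).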
